A study of Mus musculus with 6 samples.

How the data were processed

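RNA sequencing libraries from 6 samples of mouse CD4 T cells were compared, 3 labelled wild type (WT replicates 1, 2 and 4) and 3 labelled knockout (KO replicates 1, 4 and 5) for Prmt5, a protein arginine methyltransferase. Per the labels, the WT animals carried floxed Prmt5 alleles and the KO animals deleted ones. Per the labels' protocols, whole CD4 T cells from spleen and lymph nodes of C57BL/6 mice were lysed, total RNA was isolated with a column kit, ribosomal RNA was removed and strand-specific TruSeq libraries were made. The sample titles carry the word rest, whereas the treatment label of all 6 samples states stimulation through CD3 and CD28 for 48 h. The activation state of the cells is therefore open, and it is shared by both groups. A library code in the sample descriptions splits the libraries into series 22 (WT 1, WT 2 and KO 1) and series 24 (WT 4, KO 4 and KO 5).

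The submitters' processing notes name STAR, featureCounts, DESeq2 and DESeq, with no role, order or version, and the genome build GRCm38.p3. Whether counting used strand is not given in the sources used here. The deposited values are robust FPM, by the authors, that is fragments per gene scaled by robust size factors, and are treated here as RPM and not as counts. They were rounded to 1 decimal. The table held 54624 rows, of which 92 were ERCC spike-in RNAs. The spike-in rows took between 0.752% and 1.59% of a column's sum and were left out of the tests. Of the 54532 gene rows, 54409 were matched to a gene symbol by identifier without its version. The sequencing depth is unknown, and whole reads were not recovered because of the rounding, so that no interval from counting error is given. Another 6 columns of values matched none of the 6 samples by name and were not used.

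Genes with a mean of at least 1 over the 6 libraries were kept, which left 14944. Values were analysed as log2(value + 0.5), a scale that understates the change of low genes. A linear model with terms for library series and genotype was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and a two-sided moderated test. The p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 were called. All adjusted p values of genes below come from limma. The series' design text calls the 3 samples of a group biological replicates, and the p-values measure the spread between them. Coordinates are from a GRCm38 gene annotation.

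The design, 31 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists covered arginine methyltransferases, splicing factors, T cell signalling and subsets, cytokines, cell cycle, p53 targets, DNA repair, metabolism, stress and interferon responses, ribosomal proteins, mitochondrial transcripts, histones and markers of other cell types. All 31 kept at least 5 tested members, and 825 of their 828 symbols were found. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes tested, so that its direction is relative to them. By the naming rule, 14 genes were always named, together with the 5 genes of smallest p in each direction where fewer than 10 were called, and, for each list described, up to 2 members of smallest p where none was called. Of the genes this rule names, 2 are not reported here. The lists described with members are those called by camera and those on arginine methylation, splicing factors and calcium signalling.

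Alternatives changed the pseudocount (0.1 and 1), the filter (none, or a mean of at least 5), the series term, the scaling, the variance model, the threshold and the set of libraries. Subtraction of a background measured on untranscribed genes, that background as a covariate, median-of-ratios scaling and scaling to the ERCC rows were added after the data had been seen. In data simulated for this comparison on 14944 genes, with independent noise of each gene's fitted spread, 65.6% of tested genes changed 2-fold, 96.7% of those changed 4-fold and 100% of those changed 8-fold were called. Beside these, 12, 19 and 19 unchanged genes were called at the 3 sizes. With no change simulated, 0 genes were called. At each of the 3 sizes 200 genes were changed at once, and changes of fewer genes were not simulated. The adjustment is stricter where fewer genes change, so these shares need not hold for a few changed genes. Shared shifts of many genes in a library were not simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.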

Results

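The transcriptomes of CD4 T cells labelled Prmt5 WT and Prmt5 KO were compared in 3 libraries per group. PRMT5 places symmetric dimethyl marks on arginines of proteins, among them the Sm proteins of the spliceosome, and the series title links it to RNA processing and to calcium and NFAT signalling in activated T cells. The comparison addresses which transcripts differ in amount between samples labelled Prmt5 KO and samples labelled WT. Values are deposited robust FPM (sequenced fragments assigned to a gene, scaled by robust size factors, so that library sums differ) with n = 3 libraries per group, and log2 changes are KO minus WT with library series as a term. Sequencing depth is unknown, and splicing was not analysed here because the values are per gene.

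Prmt5 (ENSMUSG00000023110.12, GRCm38 chromosome 14, 54507187 to 54517525, minus strand) had a lower value in each KO library than in any WT library. It measured 34.9, 41.0 and 43.9 in WT 1, WT 2 and WT 4, and 24.4, 23.8 and 21.5 in KO 1, KO 4 and KO 5. The mean was 39.9 ± 4.59 (SD, n = 3) in WT and 23.2 ± 1.53 (SD, n = 3) in KO. The log2 change was -0.78 (SE 0.137, 95% interval -1.10 to -0.46), and it was -0.62 within series 22 and -0.94 within series 24. It did not pass the test over all genes (limma adjusted p = 1), and it passed when adjusted over the list alone, that of 11 tested arginine methyltransferases and their partners (limma adjusted p = 0.00539). That second call was lost without WT 4 (0.139), with a replicate block (0.211) and with ERCC scaling (0.5997). The value covers the whole gene, so that transcripts lacking a deleted exon would still be counted. It also covers the whole sample, so that Prmt5 RNA of other cell types would be counted too. Csf1r, a marker of myeloid cells, measured between 50.3 and 227.9 over the libraries. How much Prmt5 RNA came from such cells was not tested.

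Of 14944 genes tested, limma called 0 as higher and 0 as lower in KO. At an unadjusted p under 0.05 there were 37 genes, 12 higher and 25 lower, where chance alone would give about 747. The KO and WT values did not overlap for 431 genes, or 2.88% of those tested, where chance gives 10% for 3 against 3. Both chance figures are averages that a single split of the libraries need not approach. Over the splits into 3 and 3 fitted with the series term, limma gave 27 to 2964 genes at an unadjusted p under 0.05. The low counts are therefore no evidence that genotype has no effect. For 85.1% of genes the 95% interval of the change excluded a 2-fold difference, and for 60.1% it excluded a 1.5-fold difference. Called genes appeared in 2 other fits, 1 lower gene with a background covariate in place of the series term, and 1 higher and 4 lower genes with a replicate block.

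The genes with the smallest p lay next to each other on chromosome 2. Atrn, which encodes attractin (ENSMUSG00000027312.14, 130906495 to 131030333, plus strand), measured 86.4, 86.3 and 87.1 in the WT libraries and 44.4, 43.4 and 41.7 in the KO libraries. Its log2 change was -0.99 (SE 0.106), at -0.95 within series 22 and -1.03 within series 24, and it did not pass (limma adjusted p = 0.249). The gene 4930402H24Rik (130706200 to 130906406, minus strand) measured 25.9 ± 2.25 (SD, n = 3) in WT and 47.4 ± 0.346 (SD, n = 3) in KO, a log2 change of 0.84 (limma adjusted p = 0.848). A730017L22Rik (130873059 to 130906396, minus strand) measured 13.8 ± 2.44 in WT and 6.27 ± 0.493 in KO (SD, n = 3), a log2 change of -0.999 (limma adjusted p = 1). The latter 2 genes overlap on the same strand, so that the division of reads between them is uncertain. With the background covariate in place of the series term, Atrn passed (log2 change -0.996, limma adjusted p = 0.0235, against 0.0502 to 1 over the other fits).

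**Figure D1:**
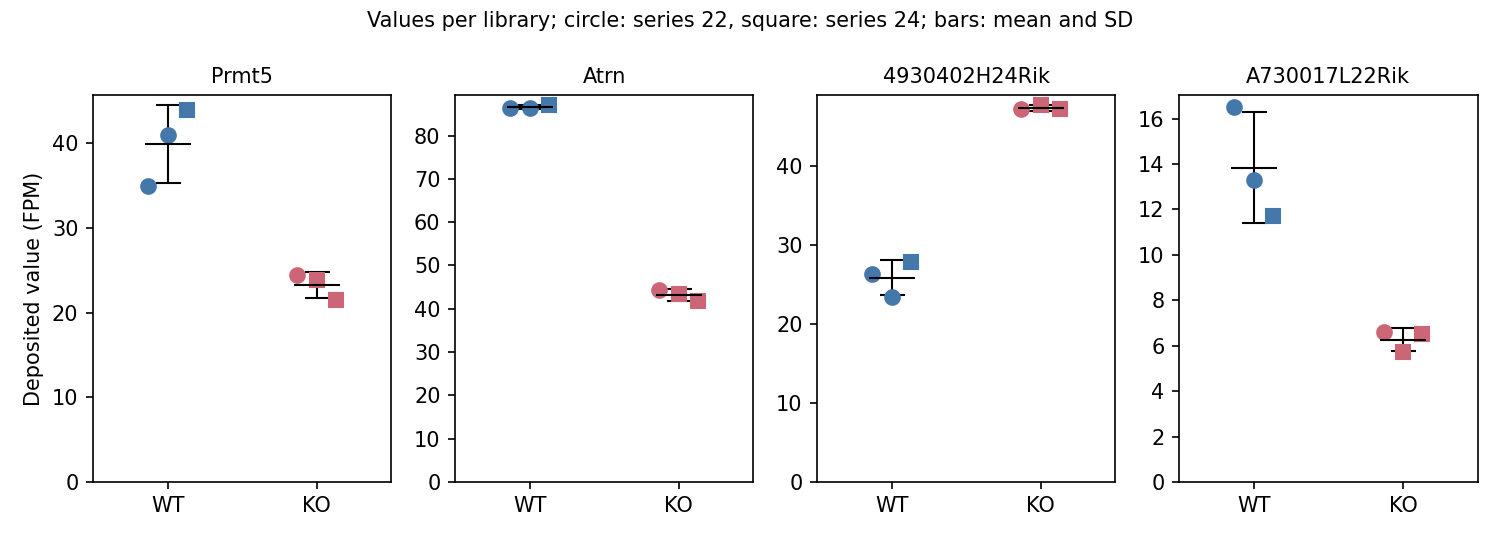
Deposited values in FPM (vertical axes, from 0) for Prmt5, Atrn, 4930402H24Rik and A730017L22Rik, with one point per library, WT in blue and KO in red, circles for series 22 and squares for series 24, and bars for the mean and SD of 3 libraries. Atrn lies between 86.3 and 87.1 in WT and between 41.7 and 44.4 in KO.

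The other genes of smallest p were low or varied between libraries, and none passed. On the higher side these were Gm9522 (log2 change 1.37), Xlr3b (0.82), Maged1 (0.50) and the immunoglobulin segment Ighv1-4 (2.68), which measured 17.2 in KO 1 and at most 0.6 in the other libraries. On the lower side, Gm42031 had a log2 change of -1.11 and the immunoglobulin segment Igkv5-39 one of -1.29.

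Genes of arginine methylation other than Prmt5 showed no called member. Wdr77, the partner of PRMT5 in the methylosome, measured 21.3 ± 3.70 in WT and 22.2 ± 3.56 in KO (SD, n = 3), with a log2 change of -0.06 that turned to 0.06 without the series term. Clns1a, which brings Sm proteins to PRMT5, had a log2 change of 0.09, and Carm1 one of 0.23. The list was not called by camera (adjusted p = 0.865), and its median of 0.06 lay on the other side of 0 from the direction of the test.

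Among splicing factors, 0 of 27 Sm and LSm genes, 0 of 25 hnRNP genes and 0 of 21 SR protein and CLK kinase genes were called over all genes, and 0 when adjusted over the list alone. The lists had median log2 changes of 0.05, -0.01 and 0.02, with camera adjusted p of 0.441, 0.830 and 0.865. Without a filter, where the median change of the 47200 genes tested was -0.08, camera called the Sm and LSm list (adjusted p = 0.00176) and the SR protein list (0.0236) toward higher values, and without KO 1 it called the hnRNP list toward lower values (0.00624). The members of smallest p were Lsm10 (log2 change 0.39) and Gemin5 (0.19), Hnrnpa0 (0.29) and Hnrnpab (0.12), and Srsf3 (0.09) and Srrm2 (-0.08).

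Calcium and NFAT signalling genes gave 0 called members of 40, over all genes and adjusted over the list alone, with a median log2 change of 0.02 (camera adjusted p = 0.865). Without a filter camera called the list toward higher values (adjusted p = 0.00566). Trpm4, a cation channel, measured 8.80 ± 0.70 in WT and 8.20 ± 0.40 in KO (SD, n = 3). Nfatc1 measured 61.2 ± 9.18 in WT and 60.3 ± 5.35 in KO (SD, n = 3), a log2 change of -0.07. The members of smallest p were Calm3 (0.18) and Trpv2 (0.19). Il2 fell under the filter and measured between 0.7 and 1.1 in all 6 libraries.

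T cell identity and cytokine genes were likewise without a called member. Cd4 had a log2 change of 0.02, the common gamma chain gene Il2rg one of -0.01, Jak3 one of 0.04 and the interleukin 2 receptor gene Il2ra one of -0.20. Camera called neither the T cell receptor list (adjusted p = 0.513), nor activation (0.513), helper cytokines (0.212), naive and central memory (0.513), regulatory (0.650), gamma-c cytokine (0.832) or gamma-delta lists (0.865). Without a filter it called the T cell receptor (0.000820), activation (0.00335), helper cytokine (0.0131), naive and central memory (0.00229) and gamma-c cytokine lists (0.0131) toward higher values. The helper cytokine list was also called higher without WT 4 (0.0175). With ERCC scaling it was called higher relative to the other genes (0.0180), at a median of -0.07 where that of all genes was -0.20. The T cell receptor list was called higher without WT 4 (0.0172) and without KO 5 (0.0412), and the activation list without WT 4 (0.0175) and without KO 4 (0.0113). Without KO 1, the T cell receptor (0.0163), activation (0.0160) and regulatory lists (0.00624) were called toward lower values.

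Camera called 12 of the 31 lists, 9 toward higher and 3 toward lower values in KO, and 0 of them held with an estimated correlation (adjusted p = 0.988 for each). These directions are relative to the other genes tested and to the deposited scaling. With ERCC scaling the median of all genes moved from 0.01 to -0.20, and with this shift the medians of 7 of the 12 lists turned from positive to negative, which left 2 positive and 10 negative. Fry called 0 lists (smallest adjusted p = 0.975). In 7 of the 12 the median change had opposite signs in series 22 and series 24. No list had a member called over all genes, and Prmt5 was the one member of the 31 lists called when adjusted over the list alone. WT 1 stood apart from the other libraries, with 0.300 FPM per kb of exon at olfactory and vomeronasal receptor genes against 0.0143 to 0.0850 elsewhere, and without it camera called 7 lists, 6 of them among the 12. Without KO 1, the one KO library of series 22, 0 of the 12 lists kept their call in the same direction. Of 14 other fits to all 6 libraries, those without a mean-variance trend and with the robust setting repeat the main camera values by construction. Over the 14 fits, the ribosomal, p53 and cholesterol lists kept their calls, with adjusted p up to 0.0268. The call was lost or turned in 8 of these fits for the glycolysis list and for the effector list, in 7 for CD8 T and NK cell markers, in 5 for mitochondrially encoded transcripts, in 3 for interferon response, in 2 for B cell markers, and in 1 each for the myeloid, mitosis and oxidative phosphorylation lists.

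Cytosolic ribosomal protein genes had a positive change in 53 of 53 members, with a median of 0.15 (camera adjusted p = 9.25e-07, and 0.988 with an estimated correlation). The median was 0.39 within series 22 and -0.08 within series 24. The mean log2 value of the list was lowest in WT 1, at 9.26, against 9.47 to 9.85 in the other libraries. The call was lost without WT 1 (camera adjusted p = 0.102) and, with the direction turned, without KO 1 (0.766). Rps2 and Rps9, with log2 changes of 0.21 and 0.18, had the smallest p. The oxidative phosphorylation list (median 0.13, camera adjusted p = 0.000999) behaved similarly, at 0.37 and -0.12 in the 2 series, with Atp5b at 0.21 and Ndufb8 at 0.18. Cholesterol synthesis genes had a median of 0.13 (camera adjusted p = 0.000999), with 0.30 in series 22 and -0.04 in series 24. Among them Mvd was at 0.25. Glycolysis genes had a median of 0.10 (camera adjusted p = 0.0422), with 0.27 and -0.12 in the 2 series, Ldha at 0.18 and Eno1 at 0.23. With an estimated correlation the adjusted p of these lists was 0.988. Without WT 1 the oxidative phosphorylation (camera adjusted p = 0.765) and glycolysis lists (0.694) also lost their calls, and the cholesterol list kept its call.

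The p53 target list had a median of 0.09 (camera adjusted p = 0.000176, and 0.988 with an estimated correlation), with 0.21 in series 22 and -0.02 in series 24. Tnfrsf10b was at 0.36 and Dcxr at 0.49. Mdm4, a regulator of p53, had a log2 change of -0.03, and Cdkn1a, a cell cycle inhibitor that p53 induces, fell under the filter at 0.4 to 1.3 in all libraries. Mitosis genes had a negative change in 31 of 38 members, with a median of -0.14 (camera adjusted p = 0.000190, and 0.988 with an estimated correlation), at -0.03 in series 22 and -0.24 in series 24. Ttk was at -0.48 and Cenpe at -0.32. The mean log2 value of the list was 2.60 in KO 4 and 3.07 to 3.30 in the other libraries. The call was lost without KO 4 (camera adjusted p = 0.448), without KO 1 (0.0515) and without a filter (0.0617). Without KO 1 the median was that of series 24. Without a filter it stayed at -0.14, where the median of all genes was -0.08. Mki67, a marker of cycling cells, measured 56.4 in KO 4 and 104.2 to 120.1 in the other libraries. DNA replication genes were not called (adjusted p = 0.970), and their median of 0.03 differed in sign from the test. They were called toward higher values without a filter (0.0131) and toward lower values without the series term (0.0465).

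Mitochondrially encoded transcripts (median -0.15, camera adjusted p = 0.0179) and interferon response genes (median -0.10, camera adjusted p = 0.0366) were negative in both series, and neither held with an estimated correlation (adjusted p = 0.988). The first had medians of -0.16 and -0.14, with mt-Nd5 at -0.25 and mt-Nd1 at -0.19. The second had a median of -0.07 in each series, with Ifi44 at -0.33 and Ifi203 at -0.14. The interferon list was called toward higher values without WT 2 (camera adjusted p = 0.0205, median 0.09). Its call was lost, with the direction of the test turned, without KO 1 (0.537) and with the replicate block (0.280), and was lost without KO 4 (0.167), without a filter (0.844) and without the series term (0.0733). The mitochondrial list lost its call without WT 1 (0.224), WT 4 (0.169), KO 1 (0.118) or KO 5 (0.289).

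Of the lists of other cell types, camera called those of myeloid cells, B cells and CD8 T and NK cells toward higher values, and none of these calls held with an estimated correlation (adjusted p = 0.988). Myeloid markers had a median of 0.32 (camera adjusted p = 0.00131), at 0.40 in series 22 and 0.07 in series 24. Their lowest values were often in WT 1, where 14 of 25 members were at their minimum. Lyz2, a lysozyme gene of myeloid cells, ranged from 19.0 in WT 1 to 482.5 in KO 5, and C1qc, a complement gene of macrophages, from 24.8 in WT 1 to 89.9 in KO 5. The call of the myeloid list was lost, with the direction of the test turned, without KO 5 (camera adjusted p = 0.679) and with the replicate block (0.703). B cell markers had a median of 0.23 (camera adjusted p = 0.0111), with H2-Eb1 at 0.40 and Cd79b at 0.32, and medians of 0.47 and 0.04 in the 2 series. CD8 T and NK cell markers had a median of 0.17 (camera adjusted p = 0.0366), at 0.37 and -0.07 in the 2 series, with Prf1 at 0.28 and Eomes at 0.25. Among T cell lists, effector and memory genes had a median of 0.13 (camera adjusted p = 0.0450, and 0.988 with an estimated correlation), at 0.38 and -0.17 in the 2 series, with Vim at 0.21 and Lgals3 at 0.55. Without KO 1 they were called toward lower values (0.0163).

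**Figure D2:**
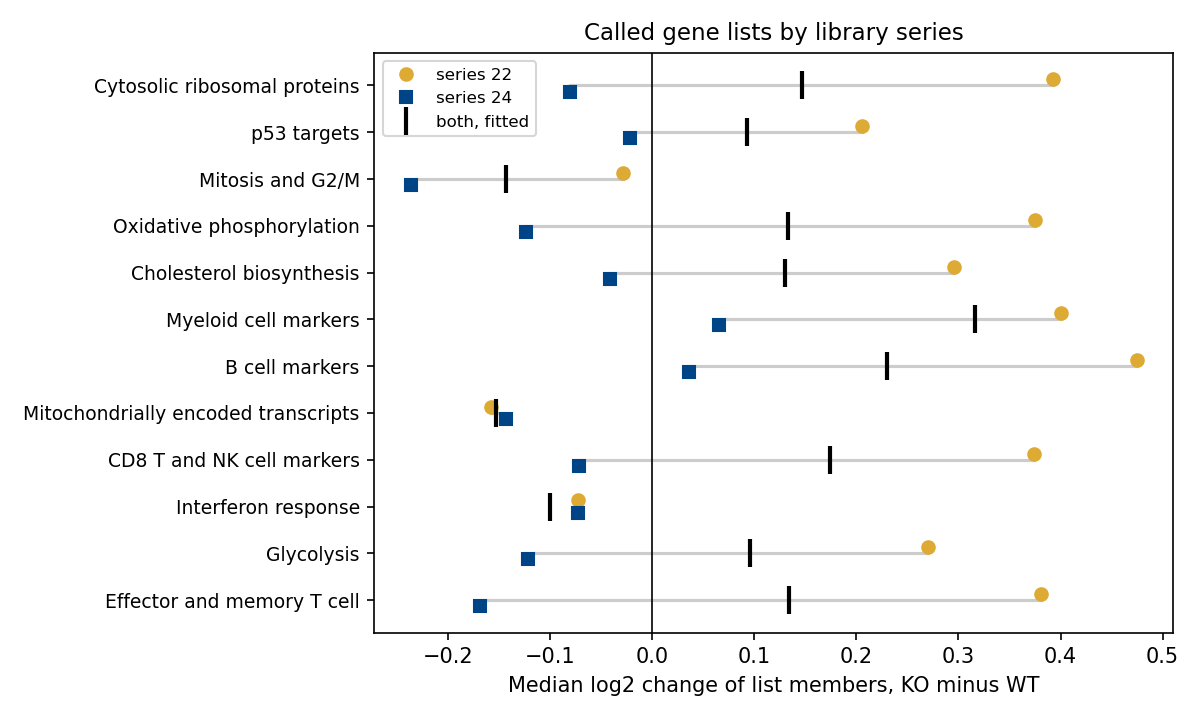
Median log2 change (horizontal axis, KO minus WT) of the members of each of the 12 called gene lists (vertical axis), within series 22 (circles), within series 24 (squares) and from the fit to all 6 libraries (black bars). In 7 lists the circle and the square lie on opposite sides of 0.

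Lists that camera did not call were DNA repair (adjusted p = 0.513), integrated stress response (0.106), immediate early and heat shock (0.0507), histones (0.688), erythroid and platelet markers (0.688) and stromal and endothelial markers (0.513). The immediate early and heat shock list lay close to the threshold, and was called toward higher values at a pseudocount of 1 (0.0395), with total-sum scaling (0.0474), without a filter (5.78e-06), without WT 4 (0.0116) and without KO 4 (0.00270), and toward lower values without the series term (0.0291). With ERCC scaling it was called higher relative to the other genes (0.0239), at a median of -0.15 where that of all genes was -0.20. Without a filter, the integrated stress response (0.000131), histone (0.00291) and erythroid and platelet lists (0.000817) were also called toward higher values. The integrated stress response list was called higher without WT 2 (0.0155) and without KO 4 (0.0183), and the erythroid and platelet list without KO 1 (0.0104). Histones were called higher without WT 2 (0.0402), WT 4 (0.0365) or KO 4 (0.00180), and lower without WT 1 (0.00132) or KO 1 (0.0160). Stromal and endothelial markers were called lower without WT 4 (0.00945) and higher without KO 1 (0.00624).

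The libraries also differed apart from genotype. The 3 libraries of series 22 had higher values of the heat shock gene Hspa1a (61.9 to 126.3) than those of series 24 (5.6 to 6.6), in both genotypes.

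**Figure D3:**
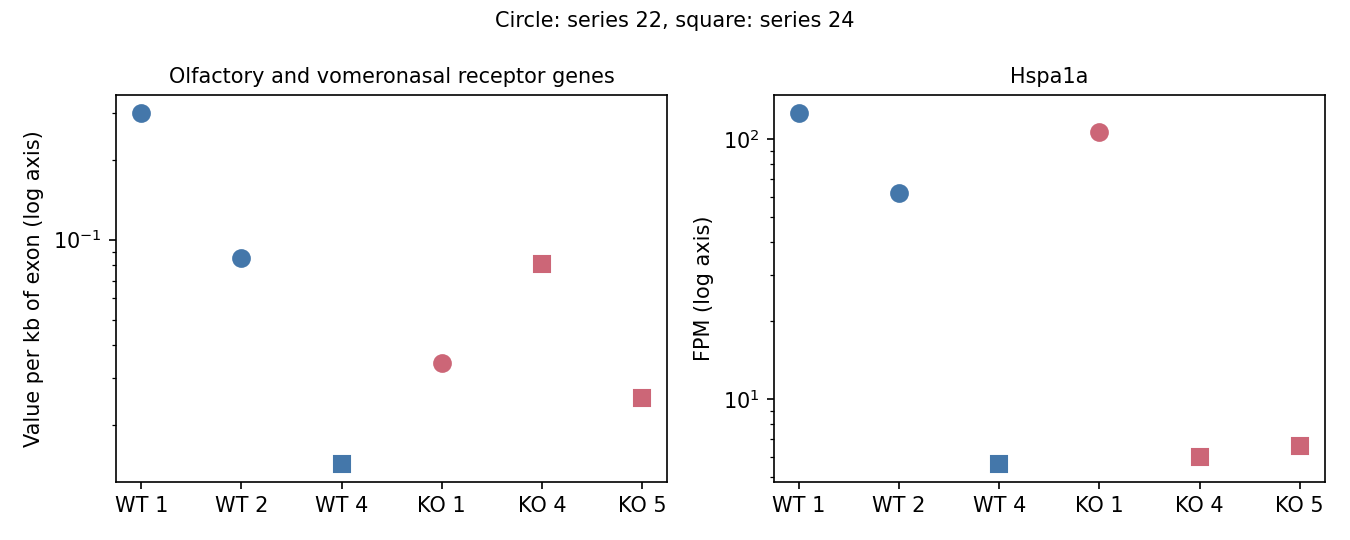
Summed value per kb of exon of 1459 olfactory and vomeronasal receptor genes (left) and the value of Hspa1a in FPM (right), on log axes, with one point per library, WT in blue and KO in red, circles for series 22 and squares for series 24. WT 1 has the highest receptor gene value, 0.300, and Hspa1a separates the series.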

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

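The test of genes gave 0 calls in either direction under most alternatives, and Prmt5 stayed lower in KO without passing under each one, with log2 changes between -0.999 (ERCC scaling) and -0.62 (without WT replicate 4). Calls appeared in 2 fits. The background rate in place of the library series, chosen after the data were seen as were the other background, median-of-ratios and ERCC fits, gave 1 lower gene, Atrn. The replicate block gave 1 higher gene (Gm22154) and 4 lower genes (Ighg3, Eps8l1, A730017L22Rik and Igkv5-39), with Prmt5 at -0.69, and 6 lists. WT and KO share only the numbers 1 and 4, and that fit has 1 residual degree of freedom. Deviations of same-numbered libraries correlated at -0.16 and -0.41. So few values, with WT replicate 1 apart from the other libraries, cannot tell whether equal numbers mark a pairing. At an unadjusted p under 0.05 the counts ran from 10 (ERCC scaling) to 463 (without WT replicate 4). Without WT replicate 4 or without KO replicate 1 the change rests on 1 library series. The count of lists was 22 without a filter, 0 with an estimated correlation, 0 with fry and 7 to 14 when a library was left out, the lowest without WT replicate 1. The number of the 12 lists that kept their call in the same direction was 0 without KO replicate 1 and 6 to 8 without any other library. Camera does not use the trend or robust setting. ERCC scaling moved the median change of all genes from 0.01 to -0.20, a shift shared by all genes that turns small positive changes by construction, among them the medians of 7 of the 12 called lists, so directions are relative to the deposited scaling. TMM factors and count models were not run, because whole reads were not recovered, and array weights gave no value because the fit did not converge. Unknown depth and values rounded to 1 decimal limit what low genes can show. The cause of the changes below was not tested.

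Adjusted over the list alone, Prmt5 lost its call without WT replicate 4 (limma adjusted p = 0.139), with the replicate block (0.211) and with ERCC scaling (0.5997), and kept it in the other fits (0.000385 to 0.0278). With ERCC scaling, the reversed values were log2 changes of Cd4 -0.20, Jak3 -0.18, Clns1a -0.13, Gemin5 -0.032, Hnrnpab -0.098, Srsf3 -0.13, Calm3 -0.036, Trpv2 -0.032, Vim -0.011, Ldha -0.040, Atp5b -0.0066, Ndufb8 -0.036, Rps2 -0.0068, Rps9 -0.042 and adjusted p of lists of Calcium and NFAT signalling 0.965. With the background rate beside the library series, the reversed values were log2 changes of Jak3 -0.0073 and adjusted p of lists of Calcium and NFAT signalling 0.961, Gamma-c cytokine receptors and JAK-STAT 0.961, Replication-dependent histones 0.821, Gamma-delta T cell markers 0.961. With the background rate in place of the library series, the reversed values were log2 changes of Cd4 -0.016 and adjusted p of lists of SR proteins and CLK kinases 0.770, Calcium and NFAT signalling 0.955, Helper T cell cytokines 0.955, T cell activation 0.409, Gamma-c cytokine receptors and JAK-STAT 0.949, Immediate early and heat shock 0.324, Replication-dependent histones 0.0552, Gamma-delta T cell markers 0.845. With the background subtracted, the reversed values were adjusted p of lists of SR proteins and CLK kinases 0.780, Calcium and NFAT signalling 0.999, Gamma-c cytokine receptors and JAK-STAT 0.941, Replication-dependent histones 0.868. With a filter at a mean of 5, the reversed values were adjusted p of lists of SR proteins and CLK kinases 0.639, Calcium and NFAT signalling 0.832, T cell activation 0.901, Gamma-c cytokine receptors and JAK-STAT 0.639, Replication-dependent histones 0.807. With fry, the reversed values were adjusted p of lists of DNA replication and G1/S 0.975. With median of ratios over the 6 libraries, the reversed values were log2 changes of Cd4 -0.019, Jak3 -0.0020 and adjusted p of lists of SR proteins and CLK kinases 0.602, Calcium and NFAT signalling 0.858, Gamma-delta T cell markers 0.973. Without a filter, the reversed values were adjusted p of lists of PRMT family and methylosome 0.238, hnRNP proteins 0.0757, Regulatory T cell 0.399, DNA replication and G1/S 0.0131, DNA repair 0.166, Stromal and endothelial markers 0.848. Without the series term, the reversed values were log2 changes of Wdr77 0.060, Mdm4 0.021 and adjusted p of lists of PRMT family and methylosome 0.845, SR proteins and CLK kinases 0.845, Helper T cell cytokines 0.684, T cell activation 0.493, Immediate early and heat shock 0.0291, Replication-dependent histones 0.493, Erythroid and platelet markers 0.546. With the replicate block, the reversed values were log2 changes of Il2rg 0.11 and adjusted p of lists of PRMT family and methylosome 0.544, hnRNP proteins 0.795, Interferon response 0.280, B cell markers 0.706, Myeloid cell markers 0.703. With total-sum scaling, the reversed values were log2 changes of Il2rg 0.018 and adjusted p of lists of hnRNP proteins 0.991.

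Lists outside the 12 were also called by camera, toward higher values relative to the other genes unless given as lower. At a pseudocount of 1 these were Immediate early and heat shock 0.0395. Without a filter these were Sm and LSm core proteins 0.00176, SR proteins and CLK kinases 0.0236, Calcium and NFAT signalling 0.00566, T cell receptor complex and proximal signalling 0.000820, Helper T cell cytokines 0.0131, T cell activation 0.00335, Naive and central memory T cell 0.00229, Gamma-c cytokine receptors and JAK-STAT 0.0131, DNA replication and G1/S 0.0131, Integrated stress response 0.000131, Immediate early and heat shock 5.78e-06, Replication-dependent histones 0.00291, Erythroid and platelet markers 0.000817. Without the series term these were DNA replication and G1/S 0.0465 (lower), Immediate early and heat shock 0.0291 (lower). With total-sum scaling these were Immediate early and heat shock 0.0474. With ERCC scaling these were Helper T cell cytokines 0.0180, Immediate early and heat shock 0.0239. Without WT replicate 1 these were Replication-dependent histones 0.00132 (lower). Without WT replicate 2 these were Integrated stress response 0.0155, Replication-dependent histones 0.0402. Without WT replicate 4 these were T cell receptor complex and proximal signalling 0.0172, Helper T cell cytokines 0.0175, T cell activation 0.0175, Immediate early and heat shock 0.0116, Replication-dependent histones 0.0365, Stromal and endothelial markers 0.00945 (lower). Without KO replicate 1 these were hnRNP proteins 0.00624 (lower), T cell receptor complex and proximal signalling 0.0163 (lower), T cell activation 0.0160 (lower), Regulatory T cell 0.00624 (lower), Replication-dependent histones 0.0160 (lower), Erythroid and platelet markers 0.0104, Stromal and endothelial markers 0.00624. Without KO replicate 4 these were T cell activation 0.0113, Integrated stress response 0.0183, Immediate early and heat shock 0.00270, Replication-dependent histones 0.00180. Without KO replicate 5 these were T cell receptor complex and proximal signalling 0.0412. With ERCC scaling the medians of these 2 lists were -0.07 and -0.15, where that of all genes was -0.20.

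Beside the reversed lists above, calls of the 12 were lost in fits to all libraries. At a pseudocount of 0.1 they were lost for Effector and memory T cell 0.0646, Glycolysis 0.0545, CD8 T and NK cell markers 0.0544. Without a filter they were lost for Mitosis and G2/M 0.0617, Interferon response 0.844, Mitochondrially encoded transcripts 0.977. With a filter at a mean of 5 they were lost for Effector and memory T cell 0.429, Glycolysis 0.156, CD8 T and NK cell markers 0.0634. Without the series term they were lost for Effector and memory T cell 0.0539, Glycolysis 0.0733, Interferon response 0.0733, B cell markers 0.155, CD8 T and NK cell markers 0.204. With the replicate block they were lost for Effector and memory T cell 0.146, Mitochondrially encoded transcripts 0.267, CD8 T and NK cell markers 0.544. With total-sum scaling they were lost for Effector and memory T cell 0.0668. With the background subtracted they were lost for Effector and memory T cell 0.193, Glycolysis 0.1298, CD8 T and NK cell markers 0.0714. With the background rate beside the library series they were lost for Effector and memory T cell 0.117, Glycolysis 0.117, Mitochondrially encoded transcripts 0.104, CD8 T and NK cell markers 0.0791. With the background rate in place of the library series they were lost for Effector and memory T cell 0.324, Glycolysis 0.308, Oxidative phosphorylation 0.0552, CD8 T and NK cell markers 0.250. With median of ratios over the 6 libraries they were lost for Glycolysis 0.0628, Mitochondrially encoded transcripts 0.0628. With ERCC scaling they were lost for Glycolysis 0.0922, Mitochondrially encoded transcripts 0.125.

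With 1 library left out in turn, log2 changes that turned sign ranged for Atp5b -0.040 to 0.47, Calm3 -0.033 to 0.40, Cd4 -0.20 to 0.25, Clns1a -0.098 to 0.28, Eno1 -0.0020 to 0.46, H2-Eb1 -0.074 to 0.88, Hnrnpa0 -0.011 to 0.59, Hnrnpab -0.019 to 0.26, Il2rg -0.14 to 0.11, Jak3 -0.20 to 0.27, Mdm4 -0.13 to 0.064, Mki67 -0.40 to 0.044, Ndufb8 -0.055 to 0.42, Nfatc1 -0.27 to 0.14, Rps2 -0.027 to 0.45, Rps9 -0.023 to 0.38, Srsf3 -0.083 to 0.26, Trpv2 -0.023 to 0.40, Wdr77 -0.11 to 0.0076. The adjusted p of lists whose direction turned ranged for Calcium and NFAT signalling 0.0515 to 0.782, Cholesterol biosynthesis 1.23e-07 to 0.881, Cytosolic ribosomal proteins 2.48e-11 to 0.766, DNA replication and G1/S 0.199 to 0.782, Effector and memory T cell 3.93e-05 to 0.708, Erythroid and platelet markers 0.0104 to 0.899, Gamma-c cytokine receptors and JAK-STAT 0.224 to 0.958, Gamma-delta T cell markers 0.0515 to 0.942, Glycolysis 0.0172 to 0.694, Helper T cell cytokines 0.0175 to 0.608, Immediate early and heat shock 0.00270 to 0.230, Interferon response 2.15e-14 to 0.537, Myeloid cell markers 1.12e-14 to 0.679, Naive and central memory T cell 0.0815 to 0.765, Oxidative phosphorylation 2.57e-05 to 0.765, PRMT family and methylosome 0.120 to 0.845, Regulatory T cell 0.00624 to 0.782, Replication-dependent histones 0.00132 to 0.640, SR proteins and CLK kinases 0.0515 to 0.873, Sm and LSm core proteins 0.0609 to 0.946, Stromal and endothelial markers 0.00624 to 0.604, T cell activation 0.0113 to 0.958, T cell receptor complex and proximal signalling 0.0163 to 0.795, hnRNP proteins 0.00624 to 0.958.

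Of the 12 called lists, these did not keep their call and direction when a library was left out, given with their camera adjusted p. Without WT replicate 1 they were Effector and memory T cell 0.708, Glycolysis 0.694, Oxidative phosphorylation 0.765, Cytosolic ribosomal proteins 0.102, Mitochondrially encoded transcripts 0.224, CD8 T and NK cell markers 0.0684. Without WT replicate 2 they were Effector and memory T cell 0.0604, Interferon response 0.0205 in the opposite direction, B cell markers 0.320, CD8 T and NK cell markers 0.116. Without WT replicate 4 they were Mitochondrially encoded transcripts 0.169, B cell markers 0.192, Myeloid cell markers 0.0845, CD8 T and NK cell markers 0.0738. Without KO replicate 1 they were Effector and memory T cell 0.0163 in the opposite direction, p53 targets 0.192, Mitosis and G2/M 0.0515, Cholesterol biosynthesis 0.881 in the opposite direction, Glycolysis 0.435 in the opposite direction, Oxidative phosphorylation 0.116 in the opposite direction, Interferon response 0.537 in the opposite direction, Cytosolic ribosomal proteins 0.766 in the opposite direction, Mitochondrially encoded transcripts 0.118, B cell markers 0.0595, Myeloid cell markers 0.0622, CD8 T and NK cell markers 0.739. Without KO replicate 4 they were Mitosis and G2/M 0.448, Cholesterol biosynthesis 0.143, Glycolysis 0.0526, Interferon response 0.167. Without KO replicate 5 they were Effector and memory T cell 0.199, Mitochondrially encoded transcripts 0.289, B cell markers 0.289, Myeloid cell markers 0.679 in the opposite direction, CD8 T and NK cell markers 0.289.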

Other observations

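All tests of explanations here were chosen after the result was seen, except that on silent gene families.

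Genes also differed between the library series. Hspa1a, a heat shock protein gene, measured 98.0 ± 32.9 in series 22 and 6.07 ± 0.503 in series 24 (SD, n = 3 libraries each), a log2 difference of -3.92 (limma adjusted p = 0.00281). Hspa1b measured 206.4 ± 63.7 and 12 ± 0.624. With genotype as a term, limma called 21 genes between the series, 20 lower and 1 higher in series 24, and among these were Tnfaip3, Nr4a1 and Jun, named after their values were seen. At an unadjusted limma p under 0.05 there were 1317 genes between the series, so the called genes need not be all that differ. No gene list was tested between the series. The WT and KO groups each hold libraries of both series, but in unequal numbers, so that series and genotype are partly confounded.

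Transcripts of the Y chromosome and Xist, an RNA of the inactive X chromosome, were found together in 4 libraries. Ddx3y measured 136 in WT 2, 95.5 in WT 4, 54.6 in KO 1 and 89.6 in KO 5, and was listed at 0 in WT 1 and KO 4. Xist ranged from 438 to 978 over all 6 libraries. Y chromosome transcripts thus differed between libraries within each group, and sex was not a term in the model. Whether a sample held cells of both sexes was not tested.

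WT 1 stood apart from the other libraries, with correlations of 0.940 to 0.973 with them over tested genes, where other pairs had at least 0.980. A pair of transcripts, Gm26870 and Gm10800, made up 16.8% of its column and 0.266% to 3.13% of the others. Genomic DNA in the library is a candidate source of its values at silent genes. As that would require, keratin-associated, defensin, taste receptor and urinary protein genes carried 0.897 times the value per kb of exon of the olfactory and vomeronasal receptor genes in WT 1, though in WT 4 the ratio was 3.37. Over 1842 abundant genes, WT 1 had a mean correlation of 0.926 with the others, and of 0.927 after the background was subtracted. The lowest value between others was then 0.949. A background at the measured rate hardly moves genes this abundant, so its subtraction could change little whatever the cause. The comparison therefore cannot decide whether DNA made the difference of abundant genes. WT 1 did reach 0.970 with WT 2, and other effects of DNA on abundant genes were not tested. The mean log2 value of ribosomal protein genes in WT 1 lay 0.211 below the range of the other libraries (SD of these 0.135). This would argue against a lower share of myeloid cells as the whole difference if that share leaves these genes unchanged. Whether it does was not tested.

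Within 99 bases of the Atrn start lie the annotated starts of 2 genes on the minus strand, which run away from Atrn. These 3 genes differed in all KO libraries from all WT libraries, 2 lower and 1 higher. A move of reads between them as the whole difference is argued against by their summed value. It changed by -29.5, from 126.3 ± 3.16 in WT to 96.8 ± 1.40 in KO (SD, n = 3). The sum cannot exclude a partial move, such as between the 2 overlapping genes on the minus strand. Genomic DNA as the cause of all 3 differences is argued against by 4930402H24Rik, whose mean was 21.5 higher in KO (SD 2.25 in WT and 0.346 in KO) where Atrn was lower, since DNA would add to both genes in the same libraries. A candidate explanation is an altered copy of the locus carried by the KO animals, since Atrn in KO was 51.3%, 50.1% and 48.2% of the WT mean, while 20 other tested genes within 500 kb had a median absolute log2 change of 0.07. Such a copy and an effect of Prmt5 loss cannot be told apart, because either would follow genotype in every library.

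The lists called by camera may owe their calls to correlation between their genes above the preset value, since 0 of the 12 stayed called with an estimated correlation, which lay between 0.243 and 0.914. A difference in 1 library series only is a further candidate for the 7 lists whose medians had opposite signs in the 2 series. Of the 9 splits of the 6 libraries that could be fitted with the series term, 4 gave at least the real number of 12 lists, with 16 the highest of the others. The splits are too few for a share under 0.05. For genes, the real split called 0, a count that all 9 of these splits, and all 10 without the series term, reach whatever they call, so that it has no bearing on chance. The highest other split called 1 gene with the series term. Without it, the split that follows the library series called 87 genes, which points to a structure of the samples by series.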
